A study of Homo sapiens with 39 samples.

How the data were processed

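Cells were grown in IMEM with 5% charcoal-stripped serum and treated for 24 hours, per the labels' protocols. Total RNA was extracted with a Qiagen kit and DNase, and stranded libraries were made with NuGEN chemistry. Per the submitters' processing notes, reads were aligned with STAR to GRCh38. Versions, the counting tool and the gene annotation are not given in the sources used here. The deposited table holds 1 TPM value per gene symbol and library, 46706 symbols by 39 libraries, and the authors' TPM values were used as they stand. Each column sums to 1000000, so sequencing depth cannot be read from it, and raw counts were not used here.

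Groups were read from the labels, 13 groups of 3 libraries. Replicate numbers follow the order of the samples and were not used to pair libraries. The design, contrasts, gene lists and alternative settings were fixed before the data were examined, apart from the later additions named below. Of 3 DMSO libraries, 2 share index sequences with treated libraries and would then have been sequenced apart from those. No pool or lane is labelled, so whether DMSO was pooled apart from all treated libraries is unknown. Comparisons with DMSO may therefore carry a pool effect. Comparisons between treated groups do not carry one that sets DMSO apart, but pools among the treated libraries were not checked.

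Symbols with a mean of at least 1 TPM over the 39 libraries were tested (14404). Values were log2(TPM + 1), and 1 model with a mean per group was fitted with limma (26 residual degrees of freedom, empirical Bayes moderation with an intensity trend). Calls were adjusted p < 0.05 by the Benjamini-Hochberg method within each comparison. Log2 differences are first group minus second, and intervals are 95% intervals from the t distribution with 26 degrees of freedom. There were 32 planned comparisons of 2 groups, an F test among the 6 ligands at each dose, and a test of whether the side chain effect differed between scaffolds at each dose. Comparisons that share the DMSO libraries were not correlated with or overlapped against each other.

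The 18 gene lists were written from general knowledge before the data were examined. They are estrogen-induced, estrogen-repressed, DNA replication, mitosis, cholesterol synthesis, endoplasmic reticulum chaperones, integrated stress response, oxidative stress, aryl hydrocarbon receptor, interferon, p53 targets, MAPK feedback and immediate early, hypoxia and glycolysis, luminal identity, basal and mesenchymal, stromal, endothelial and immune (1 list), mitochondrially encoded mRNAs, and replication-dependent histones. The 15 lists with at least 3 measured genes were tested with camera (preset correlation 0.01) and adjusted over the lists within a comparison. Each was repeated with a correlation estimated from the residuals. No symbol matched the mitochondrially encoded mRNAs, which were not analysed here. Members were also adjusted over the list alone. The mean log2(TPM + 1) of the estrogen-induced list per library was compared with the exact permutation test, whose smallest p for 3 against 3 libraries is 0.1.

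Named genes followed a rule. ESR1, PGR, GREB1, TFF1, CCND1, MYC and MKI67 were always read, as were PDZK1 and CXCL12, which failed the expression filter. Each comparison added called genes with at least 5 TPM in the higher group and no overlap between the 3 and 3 libraries (chance 10% per gene), taken by size of change, up to 10 each way at 300 nM against DMSO and 5 each way elsewhere. The text follows that order and may stop early. Lists added the members with the largest changes, and the F test its 10 smallest p values. Pseudogenes, histones and readthrough transcripts are treated as uncertain. Positions and gene types come from GENCODE version 29, which matched 83.88% of tested symbols (11100 protein-coding genes and 294 processed pseudogenes).

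Other settings fixed at the start were a pseudocount of 0.1, no expression filter (39392 genes), TPM divided by median-of-ratios factors, an estimated correlation for lists, only the libraries compared, and leaving out each library in turn. Added after the data were seen were protein-coding genes only, leaving out the 3 SAR439859 30 nM libraries, a block for replicate number, and the comparisons between scaffolds. A difference past the threshold in neither fit counts as unchanged whatever its sign. Splits of the libraries between the compared groups were all 10 for 3 against 3, and 100 random ones for the F test (ligand labels exchanged) and for the interaction (scaffold labels exchanged within the parents and within the hybrids).

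As a self-test, values were simulated from each gene's mean and SD with independent normal noise. Changes were added in 300 nM GDC-SAR to 200 of 14404 genes, drawn from those with a mean log2(TPM + 1) above 2. Genes that vary together, or libraries that share a batch, are not part of it, so it may be too favourable for these data. GDC-SAR against GDC-0810 at 300 nM recovered 68% of log2 changes of 1 and 96% of changes of 2 with 5 false calls. The F test recovered 72% and 98% with 6 false calls, and the test between scaffolds 45% and 85% with 9 false calls. Software was R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.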

Results

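RNA, coding and noncoding, was measured by stranded RNA sequencing in HCC1428-LTED cells, an estrogen receptor-positive breast cancer line adapted to growth without estrogen. Cells received vehicle (DMSO) or 1 of 6 estrogen receptor ligands at 30 or 300 nM for 24 hours. The 13 groups held 3 libraries each, 39 in all, and values are means ± SD in TPM (transcripts per 1000000), n = 3 per group. Fulvestrant, SAR439859, GDC-0810 and AZD9496 were compared with 2 hybrids. By the labels, GDC-SAR joins the GDC-0810 scaffold to the SAR439859 side chain, and AZD-SAR joins the AZD9496 scaffold to it. Libraries listed between 15818 and 26756 genes above 0, and 14404 genes were tested. Sequencing depth is unknown because the table gives TPM only. The series text speaks of duplicates while the labels give 3 libraries per group, and the replicates may be technical.

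The first question was how each ligand moved estrogen-regulated genes relative to vehicle. PGR, which encodes the progesterone receptor (chromosome 11, 101029624 to 101130524, GRCh38), averaged 35.8 ± 9.75 TPM with DMSO. At 300 nM it averaged 1.69 ± 0.179 TPM with SAR439859, 2.59 ± 0.764 with AZD-SAR, 2.63 ± 0.822 with fulvestrant, 3.45 ± 0.789 with GDC-SAR, 7.96 ± 1.19 with AZD9496 and 9.42 ± 0.506 with GDC-0810. These falls were -3.74, -3.35, -3.33, -3.03, -2.02 and -1.79 on the log2 scale (SE 0.205). GREB1, an estrogen-induced coregulator gene, fell by between 1.48 with GDC-0810 and 3.42 with AZD-SAR (SE 0.257) at that dose. The largest falls with fulvestrant were IL20, a cytokine gene, at -5.17 (SE 0.321, 67.5 ± 0.938 TPM with DMSO), and EGR3, a zinc-finger transcription factor gene, at -4.49 (SE 0.265). IL20 also led the falls with SAR439859 (-5.46), GDC-SAR (-4.67), AZD-SAR (-5.08) and AZD9496 (-3.22). With GDC-0810 the steepest falls were OVCA2 (-3.17) and the small noncoding RNA RN7SL1 (-2.83), ahead of IL20 (-2.83). The OVCA2 and RN7SL1 calls were lost without any of 5 of the 6 libraries (adjusted p 0.0588 to 0.128 and 0.0713 to 0.14) or without the expression filter (0.0791 and 0.0905), and that of OVCA2 with only the 6 libraries compared (0.0521). TFF1, a secreted trefoil peptide gene, dropped by 1.37 with AZD9496 to 2.33 with AZD-SAR (SE 0.196), and MYC dropped by 1.17 with AZD9496 to 1.86 with SAR439859 (SE 0.135).

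CCND1, which encodes cyclin D1, separated the ligands further. It averaged 267 ± 39.4 TPM with DMSO and, at 300 nM, 74.0 ± 5.69 with SAR439859 (log2 -1.83, SE 0.154), 88.7 ± 12.4 with fulvestrant (-1.58), 90.2 ± 13 with AZD-SAR (-1.55), 102.1 ± 9.75 with GDC-SAR (-1.37) and 171 ± 14.4 with GDC-0810 (-0.64). With AZD9496 it averaged 213 ± 18.4 TPM and was not called (-0.31, adjusted p = 0.265), although median-of-ratios scaling gave a call (adjusted p = 0.0378, and 0.0156 at 30 nM). The CCND1 fall with GDC-0810 at 30 nM (-0.59, adjusted p = 0.0082) was lost without DMSO replicate 1 (0.0572). MKI67, a proliferation marker gene, fell by 0.50 with 300 nM fulvestrant (adjusted p = 0.0244), 0.47 with 30 nM fulvestrant (0.0347) and 0.44 with 300 nM SAR439859 (0.0408), and each call was lost without several single libraries (adjusted p up to 0.0977, 0.116 and 0.146) or without the expression filter (0.0569, 0.0807 and 0.0938). ESR1, the estrogen receptor gene (chromosome 6, 151656691 to 152129619), averaged 436 ± 24.9 TPM with DMSO and was called with no ligand (log2 -0.41 to 0.18, SE 0.159). Its difference was -0.41 with 30 nM GDC-0810, and that became a call with median-of-ratios scaling (adjusted p = 0.0375) or with only the 6 libraries compared (0.029). The -0.34 with 300 nM AZD-SAR became a call without AZD-SAR replicate 3 (-0.50, adjusted p = 0.0247).

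**Figure D1:**
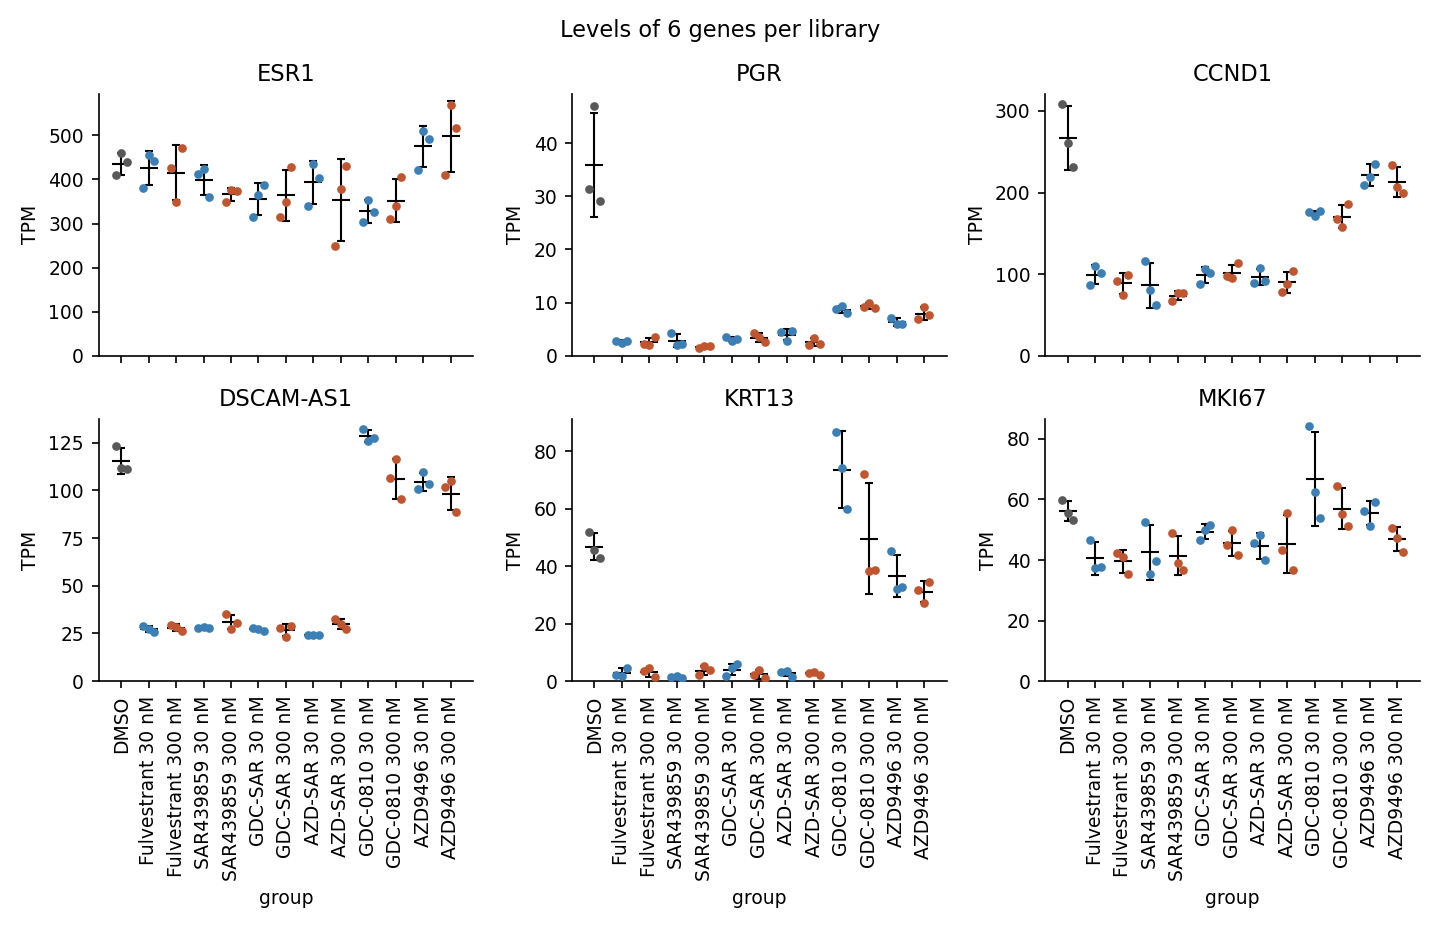
Levels of 6 genes in TPM (vertical axis) in each library of the 13 groups (horizontal axis), with group mean and SD as line and bars. PGR fell with all 6 ligands, whereas KRT13 averaged 31.1 to 73.6 TPM with GDC-0810 and AZD9496, 46.8 with DMSO and 1.39 to 4.04 with the other 4 ligands.

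The list of estrogen-induced genes (36 of 42 measured) fell with every ligand at both doses. Its mean log2(TPM + 1) was 5.67 ± 0.0899 with DMSO, and at 300 nM it was 3.98 ± 0.0255 with SAR439859, 4.15 ± 0.123 with fulvestrant, 4.15 ± 0.154 with AZD-SAR, 4.19 ± 0.0443 with GDC-SAR, 4.77 ± 0.127 with GDC-0810 and 4.93 ± 0.0900 with AZD9496. The differences from DMSO at 300 nM were -1.68, -1.52, -1.52, -1.47, -0.90 and -0.73 (SE 0.0826, exact p = 0.1 each, the smallest that 3 against 3 libraries allow). At 30 nM they were -1.61, -1.44, -1.41, -1.39, -0.82 and -0.64 in the same order. Members called lower at 300 nM numbered 30, 29, 26, 29, 26 and 15 of 36 (30, 30, 28, 31, 27 and 17 adjusted over the list alone), and camera adjusted p was at most 3.60e-21. At 30 nM they numbered 28, 28, 27, 27, 22 and 14 (31, 31, 30, 28, 26 and 16 adjusted over the list alone). The list was still called for every ligand and dose with an estimated correlation (adjusted p at most 0.00235).

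**Figure D2:**
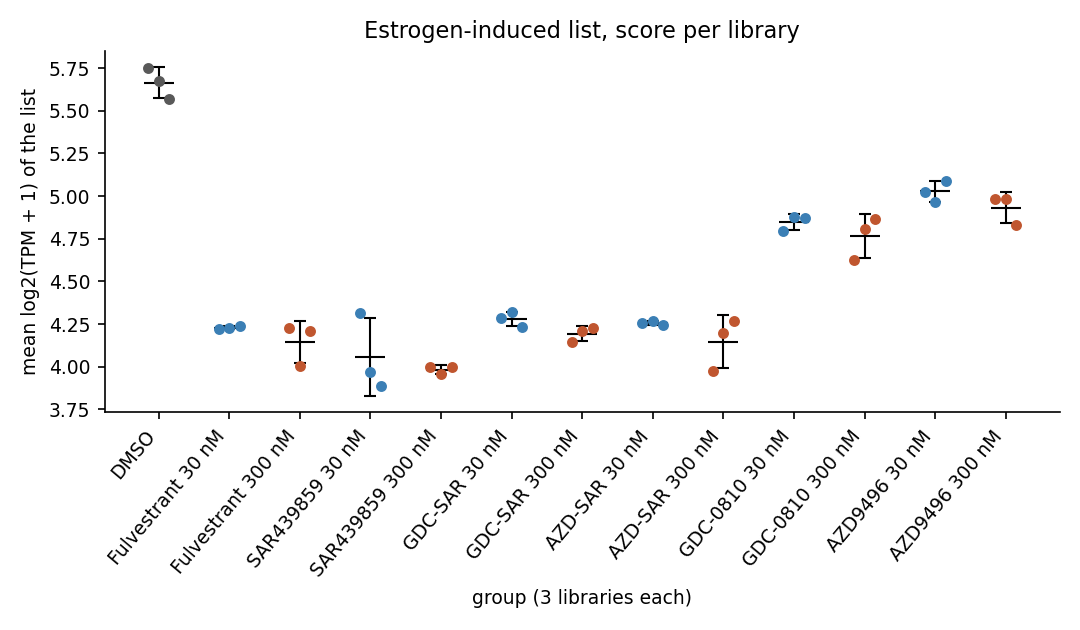
Mean log2(TPM + 1) of the 36 measured estrogen-induced genes (vertical axis) in each library of the 13 groups (horizontal axis), with group mean and SD. The level was 5.67 with DMSO, 4.77 to 5.03 with GDC-0810 and AZD9496, and 3.98 to 4.28 in the other treated groups.

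Genes that estrogen represses moved the other way. Of 14 measured list members (15 listed), 10, 10, 5, 7, 10 and 10 were higher at 300 nM with fulvestrant, SAR439859, GDC-0810, AZD9496, GDC-SAR and AZD-SAR (10, 11, 8, 9, 12 and 11 adjusted over the list alone). At 30 nM the counts were 10, 11, 7, 9, 10 and 11 (11, 11, 7, 9, 11 and 11 adjusted over the list alone). The list was called in all 12 comparisons, and only the call with 30 nM GDC-0810 was lost with an estimated correlation (adjusted p = 0.0614). With 300 nM fulvestrant, the B-cell linker gene BLNK rose by 1.83 (SE 0.183, 38.6 ± 3.24 against 10.1 ± 1.07 TPM), TP53INP1, a stress-response and autophagy gene, by 1.74 (SE 0.121, 100 ± 10.1 against 29.1 ± 1.94 TPM), CCNG2, an atypical cyclin gene, by 1.43 and the receptor kinase gene ERBB2 by 1.33.

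The largest rises were also read for each ligand at 300 nM. ABCA4, a lipid transporter gene, rose from 5.20 ± 1.33 TPM to 41.8 ± 2.82 with fulvestrant (log2 2.81, SE 0.368), and by 2.41 with SAR439859, 2.42 with GDC-0810, 2.43 with AZD-SAR and 1.99 with AZD9496. CYP1A1, a xenobiotic-metabolising enzyme gene, rose from 0.316 ± 0.0983 TPM to 10.7 ± 0.266 with SAR439859 (3.15, SE 0.218), 8.46 ± 0.651 with AZD-SAR (2.85), 7.54 ± 1.81 with fulvestrant (2.68), 5.79 ± 0.548 with GDC-SAR (2.37), 3.60 ± 1.10 with GDC-0810 (1.78) and 2.75 ± 0.531 with AZD9496 (1.5). The reticulon gene RTN2 rose by 2.58 with GDC-SAR (350 ± 29.5 against 59.8 ± 21.6 TPM). PIP, a secreted glycoprotein gene of apocrine tissue, rose by 2.46 with AZD-SAR (188 ± 70.2 against 31.9 ± 7.91 TPM) and the noncoding RNA LINC00505 rose by 2.95 (199 ± 69.6 against 23.6 ± 1.43 TPM). The pseudogene RPS21P4 rose by 2.06 to 3.29 (SE 0.474) and CHURC1-FNTB, a readthrough of neighbouring genes, by 3.04 with AZD-SAR. Both are uncertain because they share sequence with other transcripts, and the RPS21P4 call with AZD9496 was lost without AZD9496 replicate 1 (adjusted p = 0.0611).

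Called genes against DMSO at 30 and 300 nM numbered 2753 (1626 higher) and 2764 (1594 higher) with fulvestrant, 3668 (2197 higher) and 3467 (1617 higher) with SAR439859, 2417 (1145 higher) and 2309 (1007 higher) with GDC-0810, 1623 (1327 higher) and 854 (535 higher) with AZD9496, 3247 (1649 higher) and 2925 (1406 higher) with GDC-SAR, and 2968 (1721 higher) and 3682 (1835 higher) with AZD-SAR. Median-of-ratios scaling lowered the share of called genes that were higher by more than 10 points in 6 of the 12 comparisons and moved it by less in the others (up from 43.6% to 46.2% with 300 nM GDC-0810). The larger moves were from 59.1% to 45.9% and 57.7% to 47.0% with fulvestrant, 59.9% to 47.4% with 30 nM SAR439859, 81.8% to 44.1% and 62.7% to 42.8% with AZD9496, and 58% to 47.5% with 30 nM AZD-SAR. With 30 nM AZD9496 the median of all genes lay 0.18 higher before scaling than after it, so the 1327 rises are read relative to that shift. After scaling 536 of 1215 called genes were higher, and only 832 of the 1623 calls were kept. DMSO libraries may have been pooled apart from the treated ones, as 2 of the 3 carry index sequences that treated libraries also carry. The GDC-0810 counts went to 1133 at 30 nM without its replicate 1 and to 1155 at 300 nM without its replicate 1, to 1399 and 1307 without DMSO replicate 2, and to 1587 and 1431 without DMSO replicate 3. The AZD9496 counts went to 870 and 847 at 30 nM without its replicates 1 and 3, to 542 and 565 at 300 nM without its replicates 1 and 2, and to 801 and 455 without DMSO replicate 2 or 926 and 515 without DMSO replicate 3. Fulvestrant at 30 nM had 1750 without its replicate 1, GDC-SAR 2107 at 30 nM without DMSO replicate 2 and 1915 at 300 nM without its replicate 2, and AZD-SAR 1976 at 30 nM without DMSO replicate 2. With only the 6 libraries compared, the count was 1129 with 30 nM SAR439859, 1452 with 300 nM GDC-0810 and 2274 with 300 nM AZD-SAR.

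Growth-related lists were read next. Of 34 DNA replication genes, 32 were lower at each dose with fulvestrant, SAR439859, GDC-SAR and AZD-SAR, against 23 with GDC-0810 and 22 with AZD9496 at each dose (29 and 28 at 300 nM and 25 and 24 at 30 nM adjusted over the list alone). With 300 nM fulvestrant E2F2, a transcription factor gene of the cell cycle, fell by 2.40 (SE 0.337), UHRF1, needed to maintain DNA methylation, by 2.30 (SE 0.186) and the licensing factor gene CDT1 by 2.21 (SE 0.265). With 300 nM AZD-SAR the origin-loading factor gene CDC6 fell by 2.54, CCNE2 by 2.46 and MCM5 by 2.33. Every DNA replication call held with an estimated correlation. Of 34 mitosis genes, 14, 20, 7, 3, 13 and 15 were lower at 300 nM with fulvestrant, SAR439859, GDC-0810, AZD9496, GDC-SAR and AZD-SAR (17, 25, 9, 8, 14 and 18 adjusted over the list alone). At 30 nM they numbered 18, 18, 8, 3, 15 and 12 (20, 21, 9, 3, 16 and 13 adjusted over the list alone). The mitosis calls with GDC-0810 and with 30 nM AZD9496 were lost with an estimated correlation (adjusted p = 0.123 at 30 nM and 0.0724 at 300 nM, and 0.0660). The kinase genes AURKB and CDK1 fell by 1.88 and 1.74 with 300 nM fulvestrant. Of 13 replication-dependent histone genes, 12, 13, 13, 10, 13 and 13 were lower at 300 nM (13, 13, 13, 11, 13 and 13 adjusted over the list alone) and 13, 12, 11, 8, 13 and 13 at 30 nM, led by HIST1H4B (-2.68) and HIST1H1D (-2.62) with 300 nM fulvestrant. Histone values are uncertain because the copies are near identical.

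Metabolic and stress lists gave weaker answers. Of 24 cholesterol synthesis genes, 8, 13, 6, 3, 13 and 11 were lower at 300 nM in the same order of ligands (11, 14, 8, 3, 14 and 13 adjusted over the list alone) and 8, 10, 7, 3, 11 and 10 at 30 nM (10, 11, 7, 4, 11 and 13 adjusted over the list alone). With 300 nM fulvestrant the sterol isomerase gene EBP fell by 1.44 (SE 0.169), HMGCS1 by 0.998 (SE 0.149) and IDI1 by 0.84. The list was called in all 12 comparisons, and with an estimated correlation the calls were lost with 30 nM SAR439859 (adjusted p = 0.0526), GDC-0810 (0.0614 and 0.0651) and AZD9496 (0.161 and 0.109). The interferon list (16 measured) was called higher with 300 nM fulvestrant (5 members, adjusted p = 0.00286), SAR439859 (8 at 30 nM, 5.12e-04, and 3 at 300 nM, 0.0215), 300 nM GDC-0810 (1, 0.0157), GDC-SAR (8 at 30 nM, 3.91e-04, and 3 at 300 nM, 0.0179) and 30 nM AZD-SAR (5, 0.00665). All of these interferon calls were lost with an estimated correlation (adjusted p = 0.324, 0.268, 0.512, 0.402, 0.284, 0.449 and 0.364). The antiviral gene OAS1 rose by 1.91 and the ubiquitin-like modifier gene ISG15 by 1.60 with 300 nM fulvestrant, though the ISG15 call was lost without fulvestrant replicate 1 (adjusted p = 0.0533) or replicate 2 (0.0575).

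With AZD9496 the endoplasmic reticulum chaperone list was called higher (5 of 15 members at 30 nM, adjusted p = 0.0038, and 3 at 300 nM, 0.00767), and lost with an estimated correlation (0.130 and 0.156). CALR, a calcium-binding chaperone gene, rose by 1.28 with 300 nM AZD9496 (735 ± 66.9 against 303 ± 22.6 TPM) and HSPA5 by 0.58. EDEM1 rose by 0.63, a call lost without AZD9496 replicate 2 (adjusted p = 0.0601) or with only the 6 libraries compared (0.0617). The luminal identity list (6 and 2 of 17 higher, adjusted p = 0.0350 and 0.0463) was lost with an estimated correlation (0.291 and 0.279) and with scaling (0.136 and 0.0807). The oxidative stress list of 9 genes was called lower with 300 nM AZD9496 (mean -0.11, 0 members called, 1 lower adjusted over the list alone, adjusted p = 0.0489, and 0.156 with an estimated correlation). The aryl hydrocarbon receptor list, with CYP1A1, CYP1B1 and 1 other measured, was called higher with 30 nM AZD9496 (adjusted p = 0.00381, and 0.0348 with an estimated correlation). Its calls with 30 nM fulvestrant (0.0485), GDC-0810 (0.0345 at 30 nM and 0.0186 at 300 nM) and 30 nM GDC-SAR (0.0167) were lost with an estimated correlation (0.125, 0.116, 0.0724 and 0.0677). The hypoxia and glycolysis list was called lower with 30 nM SAR439859 (4 lower and 1 higher of 14, adjusted p = 0.0385, 0.11 with an estimated correlation and 0.0577 with scaling). The MAPK feedback and immediate early list of 10 genes was called with 300 nM fulvestrant (adjusted p = 0.0467, 0.225 with an estimated correlation and 0.0508 with a pseudocount of 0.1), with IER3 (-1.35) and JUN (-1.27) lower and PHLDA1 (0.71) higher. The p53 target and integrated stress response lists (16 and 13 genes) were called in none of the 12 comparisons with DMSO (lowest adjusted p 0.162 and 0.174). The basal and mesenchymal list and the stromal, endothelial and immune list each had fewer than 3 genes measured and were not tested.

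Whether the higher dose added to the lower was tested within each ligand. With limma 0 genes were called between 300 and 30 nM for any of the 6 ligands, with 255, 1713, 498, 643, 360 and 644 genes at unadjusted p < 0.05 for fulvestrant, SAR439859, GDC-0810, AZD9496, GDC-SAR and AZD-SAR. The estrogen-induced list differed by -0.08 [95% interval -0.25 to 0.09], -0.07 [-0.24 to 0.10], -0.08 [-0.25 to 0.09], -0.10 [-0.26 to 0.07], -0.09 [-0.26 to 0.08] and -0.11 [-0.28 to 0.06] in that order. With median-of-ratios scaling the difference was 0.019 with SAR439859 and 0.003 with AZD9496, and it stayed negative with the other ligands. Camera called the interferon list higher at 300 nM with fulvestrant (adjusted p = 0.00604, and 0.870 with an estimated correlation) and lower with GDC-SAR (0.0137 and 0.897). It also called the DNA replication list with GDC-0810 (0.0397 and 0.700), the aryl hydrocarbon receptor list with AZD9496 (0.0102 and 0.0989) and the histone list with AZD-SAR (0.0243 and 0.872), each with 0 members called. Without replicate 2 at 30 nM, SAR439859 had 547 called genes between the doses, and 5, 1 and 3 without 30 nM replicate 1, 300 nM replicate 1 and 300 nM replicate 3. Between 1 and 2 genes were called without fulvestrant 300 nM replicate 3 (1), GDC-0810 30 nM replicate 2 (1) or 300 nM replicates 1 (1) and 3 (2), AZD9496 30 nM replicate 2 or 300 nM replicate 2 (1 each), and GDC-SAR 30 nM replicates 1 and 2 or 300 nM replicate 3 (1 each). Without the expression filter 31 genes were called with AZD9496, 43 with GDC-SAR, 22 with AZD-SAR and 1 each with the others. With SAR439859 16 were called with a pseudocount of 0.1 and 5 with a block for replicate number. With only the 6 libraries compared, 2 were called with AZD9496 and 1 each with GDC-SAR and AZD-SAR.

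The hybrids allow the side chain to be changed on a fixed scaffold at matched doses. On the GDC-0810 scaffold KRT13, a keratin gene (chromosome 17, 41500981 to 41505705), fell from 73.6 ± 13.4 TPM with GDC-0810 to 4.04 ± 2.03 with GDC-SAR at 30 nM (log2 -3.96, SE 0.348, adjusted p = 9.35e-09). At 300 nM it fell from 49.6 ± 19.4 to 2.33 ± 1.54 TPM (-3.96, adjusted p = 9.46e-09). The fall of CLPSL2 ranked second at 30 nM (-2.78), and its call was lost without any 1 of the 6 libraries (adjusted p 0.0701 to 0.153), with a pseudocount of 0.1 (0.191) or without the expression filter (0.0573). DSCAM-AS1, a long noncoding RNA of luminal breast cancer, fell from 128 ± 3.27 to 27.1 ± 0.900 TPM at 30 nM (-2.20, SE 0.097) and from 106 ± 10.5 to 26.6 ± 3.12 TPM at 300 nM (-1.95). PGR fell by 1.22 (SE 0.205, adjusted p = 6.38e-04) and 1.24 (7.07e-04), GREB1 by 2.05 (1.19e-05) and 1.57 (6.53e-04), and CCND1 by 0.82 (0.00252) and 0.73 (0.0089). PPFIBP2, a liprin family gene, rose from 35.7 ± 6.61 to 103.5 ± 3.70 TPM at 30 nM (1.53, SE 0.216), and SLC22A4, an organic cation transporter gene, from 2.42 ± 0.725 to 7.67 ± 1.92 TPM (1.34, SE 0.224), a call lost with only the 6 libraries compared (adjusted p = 0.147). The top rise at 300 nM was COLCA1 (2.41), a call lost without GDC-0810 replicate 1 (adjusted p = 0.168) or 3 (0.0564) or GDC-SAR replicate 1 (0.143) or 2 (0.0835), or with only the 6 libraries compared (0.184). TFF1 (-0.17 [95% interval -0.58 to 0.23] and -0.30 [-0.71 to 0.10]) and ESR1 (0.12 [-0.21 to 0.44] and 0.05 [-0.28 to 0.37]) were not called.

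In all, 185 genes (84 higher) differed at 30 nM and 180 (81 higher) at 300 nM between GDC-SAR and GDC-0810. The estrogen-induced list fell by 0.57 [95% interval 0.40 to 0.74] at each dose, with 16 and 17 members lower (20 and 22 adjusted over the list alone), among them EGR3 (-2.07 and -1.99). The DNA replication list fell with 7 and 5 members lower (25 and 27 adjusted over the list alone), led by the flap endonuclease gene FEN1 (-1.07 and -0.83). Both lists held with an estimated correlation. The mitosis list had 1 member called at each dose, MYBL2 (-0.86 and -0.83), and was lost with an estimated correlation (adjusted p = 0.0575 and 0.0810). The histone list fell with 2 and 1 members called, held at 30 nM (0.00749) and was lost at 300 nM with an estimated correlation (0.0619). The estrogen-repressed list was higher with 3 and 1 members called, including TP53INP1 (0.81 and 0.77), and held with an estimated correlation (0.0143 and 0.0222). The interferon list at 30 nM (adjusted p = 1.81e-04, and 0.340 with an estimated correlation) had 0 members called. At 30 nM the count went to 106, 89 and 114 without GDC-0810 replicates 1, 2 and 3 and to 108, 110 and 98 without GDC-SAR replicates 1, 2 and 3, and at 300 nM to 96 without GDC-0810 replicate 1 and 107, 95 and 96 without GDC-SAR replicates 1, 2 and 3. With only the 6 libraries compared the counts were 22 and 3, PGR (adjusted p = 0.0514 and 0.184), CCND1 (0.0514 and 0.18) and, at 300 nM, GREB1 (0.166) and KRT13 (0.0992) were not called. Nor were EGR3 (0.0514 and 0.193), FEN1 (0.0969 and 0.263), TP53INP1 (0.0697 and 0.221) and, at 300 nM, MYBL2 (0.0958). The count at 30 nM was 281 without the 3 libraries of 30 nM SAR439859, and CCND1 at 300 nM was not called without GDC-0810 replicate 3 (0.0537) or GDC-SAR replicate 1 (0.0508) or 2 (0.0628).

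The same side chain was tested on the AZD9496 scaffold by AZD-SAR against AZD9496. KRT13 fell from 36.6 ± 7.34 to 2.79 ± 1.06 TPM at 30 nM (log2 -3.34, adjusted p = 2.55e-07) and from 31.1 ± 3.69 to 2.68 ± 0.589 TPM at 300 nM (-3.13, 6.72e-07). CITED1, a transcriptional coactivator gene, ranked next at 30 nM (-2.53), but its call was lost without any 1 of the 6 libraries (adjusted p 0.0618 to 0.136), with a pseudocount of 0.1 (0.185), without the expression filter (0.0725) and with scaling (0.058). IL17RB, an interleukin receptor gene, fell from 28.5 ± 3.29 to 4.70 ± 0.515 TPM at 30 nM (-2.37, adjusted p = 2.05e-12), and DSCAM-AS1 from 104.4 ± 4.67 to 24.2 ± 0.113 TPM. CCND1 fell by 1.20 and 1.24 (adjusted p = 1.11e-05 and 5.51e-06) and GREB1 by 1.49 and 1.53. PGR fell by 1.33 at 300 nM (adjusted p = 1.06e-04) and was not called at 30 nM (-0.57 [95% interval -0.99 to -0.15], adjusted p = 0.199). TFF1 likewise fell by 0.96 at 300 nM (0.00263) and was not called at 30 nM (-0.70, 0.0664). MYC fell by 0.55 at 300 nM (adjusted p = 0.0121), a call lost without AZD9496 replicate 2 (0.0697) or AZD-SAR replicate 1 (0.129), or with only the 6 libraries compared (0.207). ESR1 fell at 300 nM from 498 ± 80.6 to 353 ± 92.5 TPM (-0.52, SE 0.159, adjusted p = 0.0388) and was not called at 30 nM (-0.27 [-0.60 to 0.05]). That ESR1 call was lost with scaling (-0.43, 0.0542) and without the expression filter (0.0849), and it was lost without AZD9496 replicate 2 (0.205) or 3 (0.111) or AZD-SAR replicate 1 (-0.29, 0.351) or 2 (0.062). The highest-ranked rise was VGLL1 at 30 nM (1.14), a transcription cofactor gene, lost without AZD9496 replicate 2 (0.121) or 3 (0.074) or AZD-SAR replicate 2 (0.0967) or 1 (0.0521). SLC22A4 rose by 1.11 (9.34 ± 0.766 against 3.82 ± 0.839 TPM), and with only the 6 libraries compared both calls were lost (0.137 and 0.0694). At 300 nM it was SPINK8 (2.87), a protease inhibitor family gene, lost without AZD9496 replicate 2 (0.0979) or 3 (0.195) or AZD-SAR replicate 1 (0.227) or 2 (0.124), with only the 6 libraries compared (0.206), with a pseudocount of 0.1 (0.0552) or without the expression filter (0.0891).

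Between AZD-SAR and AZD9496, 242 genes (24 higher) differed at 30 nM and 1234 (312 higher) at 300 nM. The share higher was 9.92% before and 35.9% after median-of-ratios scaling at 30 nM, and 25.3% and 47.3% at 300 nM. The median of all genes lay 0.12 lower before scaling at 30 nM, and the 218 falls are read relative to it. After scaling 139 genes were lower at 30 nM, and 163 of the 242 calls were kept. The estrogen-induced list fell by 0.77 [95% interval 0.60 to 0.94] and 0.79 [0.62 to 0.96], with 16 and 21 members lower (25 and 25 adjusted over the list alone), among them CELSR2 (-1.64 and -1.88). The DNA replication list had 16 and 15 members lower (26 and 25 adjusted over the list alone), including E2F1 (-1.39 and -1.37), and the histone list 4 and 11 of 13. All 3 lists held with an estimated correlation. The mitosis list had 2 and 10 members lower, held at 30 nM (0.0201) and was lost at 300 nM with an estimated correlation (0.165). The cholesterol list had 2 and 7 members lower, led by HMGCS1 (-0.81 and -0.84), held at 30 nM (0.0153) and was lost at 300 nM (0.130) with an estimated correlation. The hypoxia and glycolysis list had 2 and 4 members lower, held at 30 nM (0.0381) and was lost at 300 nM (0.130) with an estimated correlation. Its glucose transporter gene SLC2A1 fell from 127 ± 7.76 to 52.6 ± 5.44 TPM at 30 nM (-1.26, SE 0.119) and from 127 ± 19.3 to 49.1 ± 3.04 TPM at 300 nM. The estrogen-repressed list was higher with 1 and 3 members called, held at 30 nM (0.0495) and was lost at 300 nM (0.180) with an estimated correlation, and the interferon list at 30 nM had 0 members called (2.18e-04, and 0.259 with an estimated correlation). At 300 nM the count went to 320 and 643 without AZD9496 replicates 2 and 3, and to 289, 504 and 2702 without AZD-SAR replicates 1, 2 and 3. At 30 nM it went to 149 and 133 without AZD9496 replicates 2 and 3 and to 139, 153 and 139 without AZD-SAR replicates 1, 2 and 3, and with only the 6 libraries compared the counts were 59 and 20, without GREB1 (adjusted p = 0.0561 and 0.0801) and, at 300 nM, PGR (0.102), TFF1 (0.128), CCND1 (0.0547) and ESR1 (0.306). That setting also lost HMGCS1 (0.126 and 0.117) and, at 300 nM, CELSR2 (0.0669) and E2F1 (0.0921). At 300 nM the count was 818 without the expression filter and 2206 with a block for replicate number.

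**Figure D3:**
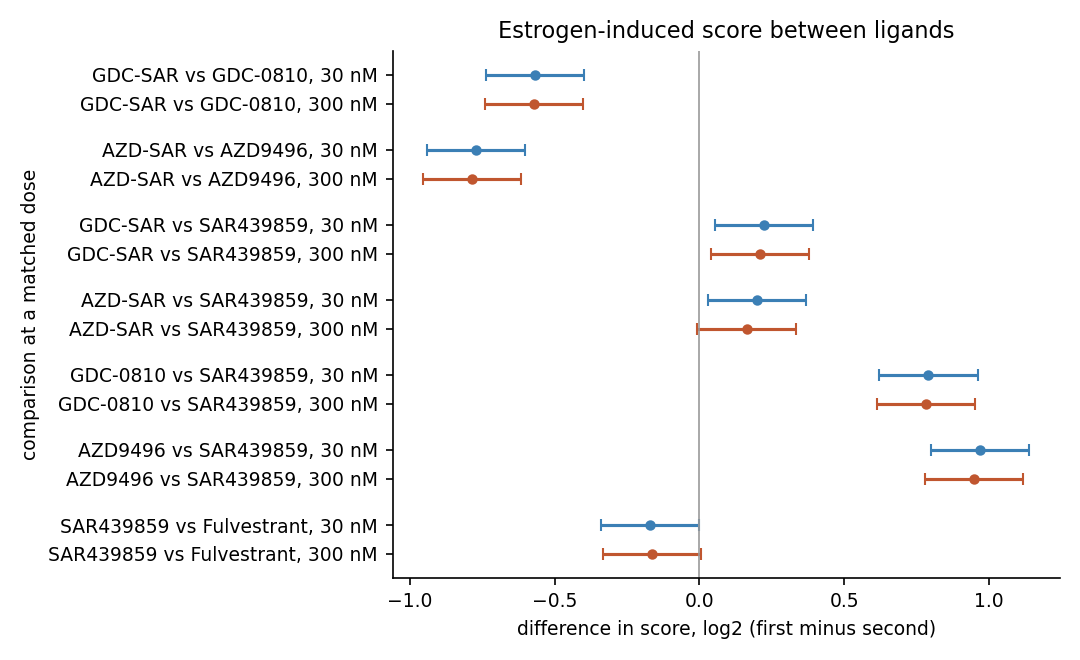
Difference in the mean log2(TPM + 1) of 36 estrogen-induced genes (first named minus second) for 7 comparisons at 30 and 300 nM, with 95% intervals as bars. The intervals use 1 spread taken from all 13 groups. With the side chain changed to that of SAR439859, the level was lower by 0.57 on the GDC-0810 scaffold and by 0.77 and 0.79 on the AZD9496 scaffold.

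The side chain effects on the scaffolds were compared through libraries that the comparisons do not share. At 30 nM 82 genes were lower with both hybrids than with their parents, of 218 called lower on the AZD9496 scaffold (1.53 expected if independent), and at 300 nM 79, of 922 (6.34 expected). For rises 17 genes were shared of 84 and 24 (0.14 expected), and 34 of 81 and 312 (1.76 expected). Both comparisons take each gene's spread from the same fit, which favours genes of low spread in both. The expected counts may therefore be too low. Over all 14404 genes the 2 side chain effects correlated at 0.208 and 0.131. The difference between the side chain effects (effect on the GDC-0810 scaffold minus effect on the AZD9496 scaffold) was 0.20 [95% interval -0.04 to 0.44] and 0.21 [-0.03 to 0.45] for the estrogen-induced list. With median-of-ratios scaling it was 0.053 and 0.111. With limma 0 genes were called for that difference at 30 nM (768 at unadjusted p < 0.05) and 1 at 300 nM (2200 at unadjusted p < 0.05). The 1 gene was GLT8D1, a glycosyltransferase family gene (1.40, SE 0.235, adjusted p = 0.0243), which rose with the side chain by 0.93 (SE 0.166) on the GDC-0810 scaffold and was not called on the AZD9496 scaffold (-0.47, adjusted p = 0.0691). The GLT8D1 call was lost, to 0 genes, without GDC-0810 replicate 1 (0.0832) or 2 (0.117), AZD9496 replicate 1 (0.0685) or 3 (0.126), GDC-SAR replicate 1 (0.0579), 2 (0.0544) or 3 (0.175), or AZD-SAR replicate 1 (0.0821). It was also lost with only the libraries compared (0.36), where 4 other genes were called, as was its rise on the GDC-0810 scaffold (0.166). At 300 nM 3 genes were called without GDC-0810 replicate 3 and 567 without AZD-SAR replicate 3, at 30 nM 1 without GDC-SAR replicate 1, and with a block for replicate number 243 at 300 nM. Without the expression filter 3 and 10 genes were called, and at 300 nM 2 with protein-coding genes only and 3 without the 30 nM SAR439859 libraries.

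The hybrids were then set against SAR439859, whose side chain they carry. With GDC-SAR, 37 genes (18 higher) differed at 30 nM and 0 at 300 nM (limma, 658 at unadjusted p < 0.05). At 30 nM the sense intronic noncoding RNA BACH1-IT3 rose by 2.63 (SE 0.44, adjusted p = 0.00463) and YAF2 by 1.56. NPY1R, a neuropeptide Y receptor gene, rose by 1.52 (SE 0.212, adjusted p = 8.58e-04), and MTRNR2L12 fell by 1.40. Without SAR439859 replicate 3 the BACH1-IT3 (adjusted p = 0.0595), YAF2 (0.0595) and MTRNR2L12 (0.0873) calls were lost, while that of NPY1R was kept. With AZD-SAR, 8 genes (3 higher) differed at 30 nM and 0 at 300 nM (limma, 882 at unadjusted p < 0.05), led by BACH1-IT3 (2.45, adjusted p = 0.035) and FANCA (-1.24). Both calls were lost without SAR439859 replicate 3 (adjusted p = 0.269 and 0.418) or AZD-SAR replicate 1 (0.0507 and 0.195), 2 (0.117 and 0.133) or 3 (0.0855 and 0.0829). The estrogen-induced list lay 0.22 [95% interval 0.05 to 0.39] and 0.21 [0.04 to 0.38] higher with GDC-SAR, and 0.20 [0.03 to 0.37] and 0.16 [-0.01 to 0.33] higher with AZD-SAR. These intervals take 1 spread from all 13 groups, whereas SAR439859 at 30 nM had an SD of 0.227, so they may be too narrow there. The exact permutation test gave p = 0.3 and 0.1 with GDC-SAR and 0.4 and 0.3 with AZD-SAR. Camera called the list higher in all 4 (adjusted p = 1.13e-04, 8.88e-07, 5.00e-04 and 0.00299), and each call was lost with an estimated correlation (0.39, 0.117, 0.528 and 0.77). Also lost that way, each with 0 members called, were the DNA replication list with GDC-SAR (0.253 and 0.0614) and 30 nM AZD-SAR (0.492) and the mitosis list with GDC-SAR (0.546 and 0.0614) and 300 nM AZD-SAR (0.775). With 300 nM GDC-SAR so were the histone (0.279), endoplasmic reticulum chaperone (0.279) and estrogen-repressed (0.341) lists. PGR differed by 0.15 [-0.27 to 0.57] and 0.71 [0.29 to 1.13] with GDC-SAR and by 0.40 [-0.02 to 0.82] and 0.40 [-0.03 to 0.82] with AZD-SAR, none called. The GDC-SAR count at 30 nM went to 215, 785 and 1 without SAR439859 replicates 1, 2 and 3 and to 20, 15 and 10 without GDC-SAR replicates 1, 2 and 3. That of AZD-SAR at 30 nM went to 197, 407 and 2 without SAR439859 replicates 1, 2 and 3, and to 1 without AZD-SAR replicate 1, 2 or 3, and with only the 6 libraries compared both were 0. At 300 nM that setting called 3 genes with GDC-SAR and 2 with AZD-SAR. Without the expression filter the counts were 85 and 12 with GDC-SAR and 22 and 29 with AZD-SAR, and scaling gave 65 and 34 at 30 nM. At 30 nM GDC-SAR had 56 with a pseudocount of 0.1, 65 with protein-coding genes only and 108 with a block for replicate number, and at 300 nM AZD-SAR had 1 without the 30 nM SAR439859 libraries.

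The parents were compared with SAR439859 in the same way. GDC-0810 differed in 887 genes (346 higher) at 30 nM and 355 (202 higher) at 300 nM, and AZD9496 in 770 (612 higher) and 1024 (804 higher). Scaling moved the share higher from 39% to 58.1% with 30 nM GDC-0810, and from 79.5% to 59.9% and 78.5% to 58.3% with AZD9496. KRT13 was higher by 4.97 and 3.42 with GDC-0810 (SE 0.348) and by 3.98 and 2.83 with AZD9496. EGR3 was second with 30 nM GDC-0810 (2.73), CITED1 with 300 nM GDC-0810 (2.98), and RAPGEFL1, a guanine nucleotide exchange factor gene, with 30 nM AZD9496 (2.79). With 300 nM AZD9496 CITED1 (2.94), LINC01016 (2.80), RAPGEFL1 (2.45) and the glycoprotein hormone gene STC1 (2.40) were among the 5 largest rises. PGR was higher by 1.37 and 1.95 with GDC-0810 and 0.97 and 1.73 with AZD9496, and CCND1 by 1.05 and 1.19 and by 1.39 and 1.51. ESR1 was not called, at -0.28 [95% interval -0.61 to 0.04] and -0.07 [-0.39 to 0.26] with GDC-0810, and 0.25 and 0.43 [0.10 to 0.76] with AZD9496, the last of which became a call without AZD9496 replicate 1 (0.56, adjusted p = 0.0499). COLCA1 led the falls with 300 nM GDC-0810 (-2.38), a call lost without SAR439859 replicate 1 (adjusted p = 0.0543) or 3 (0.075) or GDC-0810 replicate 1 (0.101). The estrogen-induced list was higher by 0.79 [0.62 to 0.96] and 0.78 [0.61 to 0.95] with GDC-0810, with 19 and 17 members called (25 and 24 adjusted over the list alone). It was higher by 0.97 [0.80 to 1.14] and 0.95 [0.78 to 1.12] with AZD9496, with 23 and 22 (27 and 25 adjusted over the list alone). The DNA replication list was higher with 22 and 19 members called with GDC-0810 and 26 and 21 with AZD9496, and both lists held with an estimated correlation. The mitosis list (7 and 3 members called with GDC-0810, 9 and 9 with AZD9496) and the histone list (8 and 5, and 10 and 11) were higher and held as well. The estrogen-repressed list was lower (6 and 4 members with GDC-0810, 3 and 4 with AZD9496) and was lost with an estimated correlation with 300 nM AZD9496 (adjusted p = 0.0545). Calls lost with an estimated correlation were those of the cholesterol list with 300 nM GDC-0810 (0.246) and AZD9496 (0.0803 and 0.0653), the interferon list with 30 nM GDC-0810 (0.542) and AZD9496 (0.181 and 0.62), and with AZD9496 the hypoxia list (0.0521 and 0.113) and, at 300 nM, the aryl hydrocarbon receptor list (0.113). The GDC-0810 count at 30 nM went to 1639 and 536 without SAR439859 replicates 2 and 3, and to 485, 526 and 578 without GDC-0810 replicates 1, 2 and 3. The AZD9496 count went to 1886 and 432 at 30 nM without SAR439859 replicates 1 and 3, to 438 without AZD9496 replicate 3, and at 300 nM to 377 and 672 without SAR439859 replicates 1 and 2 and 395 without AZD9496 replicate 2. With only the 6 libraries compared the counts were 6 and 25 with GDC-0810 and 13 and 244 with AZD9496, and at 30 nM PGR (adjusted p = 0.24 and 0.396) and CCND1 (0.257 and 0.164) were not called, nor were RAPGEFL1 with 30 nM AZD9496 (0.214) and COLCA1 with 300 nM GDC-0810 (0.0954). A block for replicate number gave 1630 with 300 nM AZD9496.

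Few genes separated SAR439859 from fulvestrant. At 30 nM 2 genes were called lower with SAR439859 (limma, 1271 at unadjusted p < 0.05), BACH1-IT3 (-2.41, SE 0.44, adjusted p = 0.0458) and CAP2, an actin-regulating gene (-0.83, SE 0.147, 5.29 ± 0.987 against 10.1 ± 1.02 TPM). At 300 nM 0 were called (limma, 614 at unadjusted p < 0.05). Both calls were lost with scaling (adjusted p = 0.0579 each), and the count went to 0 without fulvestrant replicate 1 or 2 or SAR439859 replicate 1 or 3 and to 273 without SAR439859 replicate 2. With only the 6 libraries compared both calls were lost (adjusted p = 1 each) and 2 other genes were called at 30 nM and 4 at 300 nM. The BACH1-IT3 call was lost without the expression filter (0.0896), with a block for replicate number (0.0673) and without fulvestrant replicate 3 (0.21). At 30 nM 4 genes were called with a pseudocount of 0.1 and 1 each with the block and with protein-coding genes only. At 300 nM 1 gene was called without fulvestrant replicate 2 or 3. PGR differed by 0.03 [95% interval -0.39 to 0.45] and -0.41 [-0.83 to 0.01], and ESR1 by -0.09 [-0.42 to 0.23] and -0.17 [-0.50 to 0.16]. The estrogen-induced list was lower by 0.17 [0.00 to 0.34] and 0.16 [-0.01 to 0.33], and its camera calls (adjusted p = 0.00364 and 0.0113) were lost with an estimated correlation (0.563 and 0.418), as were those of the interferon list at 30 nM (0.563) and of the mitosis and MAPK feedback lists at 300 nM (0.418 each). For the means of the estrogen-induced list the exact permutation test gave p = 0.4 and 0.1.

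An F test asked which genes differed among the 6 ligands at a dose. It called 736 genes at 30 nM and 707 at 300 nM. DSCAM-AS1 (chromosome 21, 40383083 to 40385358) ranked first at both doses (F = 246 and 180.5, adjusted p = 6.07e-19 and 5.00e-17), followed by STC1 and IL17RB. DSCAM-AS1 averaged 115 ± 6.75 TPM with DMSO and was called with neither dose of GDC-0810 (0.15 and -0.12) nor AZD9496 (-0.14 and -0.23), but fell by 1.87 to 2.20 with the other 4 ligands (with scaling, 30 nM AZD9496 gave a call at -0.35, adjusted p = 0.0425). STC1 behaved alike, at 0.08 and -0.14 with GDC-0810, -0.14 and 0.00 with AZD9496, and -2.39 to -1.73 with the others. SLC7A5, an amino acid transporter gene, averaged 90.8 ± 6.18 TPM with DMSO and fell by 1.55 to 1.91 with fulvestrant, SAR439859 and both hybrids, against 0.04 and 0.01 with AZD9496. CXCL14, a chemokine gene, went in opposite directions. It fell by 0.77 to 1.40 with fulvestrant, SAR439859 and the hybrids and rose with GDC-0810 by 0.58 (adjusted p = 0.00506) and 0.48 (0.0185). The CXCL14 rise with GDC-0810 was lost at 30 nM without its replicate 1 (0.0538), and at 300 nM without its replicate 1 (0.132) or DMSO replicate 1 (0.0628), or with only the 6 libraries compared (0.0549). The F test counts were 433 and 273 within the libraries of 1 dose alone and 1243 and 1761 with a block for replicate number, and they went to 489 without AZD9496 30 nM replicate 3, 1159 and 1178 without SAR439859 30 nM replicates 1 and 2, 389 without AZD9496 300 nM replicate 2, 1491 without AZD-SAR 300 nM replicate 3 and, at 300 nM, 1148 without the 30 nM SAR439859 libraries.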

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

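The tests of the DMSO pool, of pseudogenes, of a shift or mixture in SAR439859 replicate 1 and by splits were chosen only after the results were seen. The comparison of side chain effects and the test of zeros in SAR439859 replicate 3 were not.

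Each result below was flagged because an effect of the side chain differed between the GDC-0810 and AZD9496 scaffolds at adjusted p < 0.05. For GLT8D1 at 300 nM the difference was 1.40 (adjusted p = 0.0243), with a rise of 0.93 on the GDC-0810 scaffold and -0.47, not called, on the AZD9496 scaffold. For the cholesterol synthesis list at 30 nM the difference was 0.287 (adjusted p = 0.0156), lost with an estimated correlation (0.348) and with median-of-ratios scaling (0.133, adjusted p = 0.143). For the replication-dependent histone list at 300 nM it was 0.531 (adjusted p = 0.0025), lost with an estimated correlation (0.499), and histone copies share reads. Scaffold labels were exchanged at random within the parents and within the hybrids. Chance is not excluded for the count of 1 gene at 300 nM, as 11 of 100 splits gave as many. The highest, 1951, points to structure among the samples, and its source was not tested. The count of 1 gene does not test GLT8D1 itself. At 30 nM 0 genes were called, which any split reaches (100 of 100, highest other 1), so the splits decide nothing there.

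Differences from DMSO might come from separate pooling of the DMSO libraries instead of the ligands, which was tested with 300 nM AZD-SAR alone. Of genes lower with 300 nM AZD-SAR than with DMSO, 70.4% were higher with GDC-0810 than with SAR439859 at 300 nM, against 47.2% of genes not called. The means of those GDC-0810 and SAR439859 libraries did not enter the choice of genes, but their spread did, through the shared fit. Of genes higher with AZD-SAR, 65.6% were lower with GDC-0810 than with SAR439859, against 52.2%. A pool effect as the whole cause predicts shares within 5 points. The shares lay further apart, which argues against it as the whole cause for these sets of genes, but not for each gene in them. Pools among the treated libraries were not checked, and a pool difference between GDC-0810 and SAR439859 might also move the shares. A pool effect stays open in part here and for the other 11 comparisons with DMSO. The choice of GDC-0810 against SAR439859 was made after scaling shifts had been seen.

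Processed pseudogenes (294 tested) had a median above DMSO in 12 of 12 treated groups, from 0.22 with 300 nM GDC-SAR to 0.48 with 300 nM fulvestrant. If antagonism were the whole cause, the shift with GDC-0810 and AZD9496 should be at most 70% of that with SAR439859, a bound set after the medians were seen. It was 85.1% together, 93.3% with GDC-0810 and 76.9% with AZD9496, and after median-of-ratios scaling 79.5%, 101.7% and 57.3%, while the fall of the estrogen-induced list was 46.9%. The hybrids lowered the estrogen-induced list further than their parents, so antagonism alone would put their pseudogene medians above those of the parents. GDC-SAR differed from GDC-0810 by -0.132 and -0.134 (-0.152 and -0.145 scaled), and AZD-SAR from AZD9496 by -0.021 and 0 (0.052 and 0.058 scaled). No spread was estimated for these medians. As the ratios fall on both sides of the bound and the hybrids go both ways after scaling, antagonism is not excluded. A pool difference may account for the rise too, but a ligand effect common to all 6 predicts the same 12 of 12. The 2 cannot be told apart because any such pool difference would go with DMSO.

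The 3 libraries of 30 nM SAR439859 had the widest spread in the estrogen-induced list of any group (SD 0.227), and MALAT1, an abundant nuclear RNA named here after its values were seen, was listed at 0 TPM in replicate 1 (98150 and 103000 in replicates 2 and 3) and in replicate 2 of 300 nM AZD-SAR. The list mean of replicate 1 lay 0.386 above that of replicates 2 and 3 (in other groups at most 0.18 above and 0.261 below) and 0.127 above after median-of-ratios scaling (at most 0.113 above and 0.161 below), so a shift of all its genes may account for part of the gap, and whether for all of it stays open. Taking MALAT1 out of the totals left 0.259 (at most 0.248 above). Less affected cells mixed into replicate 1 might add to it. Over 54 genes, in a test set after levels of several had been seen, its median level lay 3.25% (quartiles -3.22% and 9.35%) of the way from 300 nM SAR439859 to DMSO. This is below the 10% predicted, which argues against 10% or more of cells at the DMSO level. A larger share of partly affected cells stays open, because the scale runs to DMSO only. A thin library is a possible reason for replicate 3, with 30.7% zeros among tested genes under 3 TPM (median elsewhere 6.32%) but 0.0887% among those at 100 TPM or more. Replicate 2 and the median elsewhere also had 0.0887% at that level, so that share could not single out a thin library. Sequencing depth is unknown, and the reason stays open.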

How the results depend on the processing

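The replicate block, protein-coding genes only, the set without SAR439859 30 nM libraries and the tests of scaffold comparisons were chosen after results were seen. Falls of the estrogen-induced list against DMSO and between each hybrid and its parent kept their camera call with the other pseudocount, with scaling and with an estimated correlation, and their means kept an interval clear of 0 without the filter. Lists were not run with single libraries left out. Pairs of values are 30 and 300 nM. The limits are 3 libraries per group, TPM without counts, DMSO index sequences shared with treated libraries, and gene totals that scaling shifts. The cause of the changes below was not tested.

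With only the libraries compared, called genes were 1129 with 30 nM SAR439859, 1452 with 300 nM GDC-0810 and 2274 with 300 nM AZD-SAR against DMSO. Between doses they were 2 with AZD9496, 1 with GDC-SAR and 1 with AZD-SAR. They were 22 and 3 for GDC-SAR against GDC-0810, 59 and 20 for AZD-SAR against AZD9496, 0 and 3 for GDC-SAR and 0 and 2 for AZD-SAR against SAR439859, 6 and 25 for GDC-0810 and 13 and 244 for AZD9496 against SAR439859. They were 2 (neither called before) and 4 for SAR439859 against fulvestrant, 0 and 0 for AZD9496 against GDC-0810, 1 for AZD-SAR against GDC-SAR at 30 nM, 4 for the difference between side chain effects at 300 nM, and 433 and 273 for the F test.

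Without the filter the doses differed in 1 gene each with fulvestrant, SAR439859 and GDC-0810, 31 with AZD9496, 43 with GDC-SAR and 22 with AZD-SAR. AZD-SAR against AZD9496 had 818 at 300 nM, GDC-SAR against SAR439859 85 and 12, AZD-SAR against SAR439859 22 and 29, AZD9496 against GDC-0810 36 and 27, AZD-SAR against GDC-SAR 13 and 50, and the difference between side chain effects 3 and 10. The list mean became 0.167 for AZD-SAR against SAR439859 at 300 nM, -0.146 for SAR439859 against fulvestrant and 0.121 for AZD9496 against GDC-0810 at 30 nM. With a pseudocount of 0.1 there were 16 genes between SAR439859 doses, 56 for GDC-SAR against SAR439859 and 4 for SAR439859 against fulvestrant at 30 nM, and AZD9496 against GDC-0810 had a list mean of 0.19.

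Median-of-ratios scaling gave 65 for GDC-SAR and 34 for AZD-SAR against SAR439859 and 0 for SAR439859 against fulvestrant at 30 nM, and 0 and 17 for AZD9496 against GDC-0810. List means became 0.151 for AZD-SAR against SAR439859 and -0.1 for SAR439859 against fulvestrant at 300 nM, and the one for AZD9496 against GDC-0810 at 30 nM reversed to -0.01. Protein-coding genes only gave 65 for GDC-SAR against SAR439859 and 1 for SAR439859 against fulvestrant at 30 nM, 0 and 0 for AZD9496 against GDC-0810, and 2 for the difference between side chain effects at 300 nM. Without the 30 nM SAR439859 libraries there were 281 for GDC-SAR against GDC-0810 at 30 nM, 1 for AZD-SAR against SAR439859 at 300 nM, 193 and 610 for AZD9496 against GDC-0810, 3 for the difference between side chain effects and 1148 for the F test at 300 nM. With an estimated correlation the estrogen-induced list was not called for GDC-SAR against SAR439859 (0.223 and 0.21, adjusted p = 0.39 and 0.117), AZD-SAR against SAR439859 (0.198 and 0.163, adjusted p = 0.528 and 0.77) or SAR439859 against fulvestrant (-0.172 and -0.164, adjusted p = 0.563 and 0.418).

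A block for replicate number gave 5 between SAR439859 doses, 2206 for AZD-SAR against AZD9496 at 300 nM, 108 for GDC-SAR against SAR439859 at 30 nM, 1630 for AZD9496 against SAR439859 at 300 nM, 1 for SAR439859 against fulvestrant at 30 nM, 590 and 1213 for AZD9496 against GDC-0810, 1 for AZD-SAR against GDC-SAR at 30 nM, 243 for the difference between side chain effects at 300 nM, and 1243 and 1761 for the F test. Residuals of libraries with the same number correlated at 0.064 on average (0.111, 0.01 and 0.073 for numbers 1, 2 and 3), against -0.032 otherwise. Of 39 libraries, 29 were closest to their own number. Libraries with the same number thus tended to deviate together, least for number 2. A batch may lie behind this, and none is labelled. The main counts come from a fit without this block, so few or 0 calls there do not show that groups were alike.

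Leaving out 1 library, counts against DMSO ranged over 1750 to 2296 and 1868 to 2527 with fulvestrant, 2642 to 3909 and 2353 to 3305 with SAR439859, 1133 to 2167 and 1155 to 2536 with GDC-0810, 801 to 1463 and 455 to 594 with AZD9496, 2107 to 2567 and 1915 to 2811 with GDC-SAR, and 1976 to 2405 and 2591 to 4194 with AZD-SAR. Between doses they ranged over 0 to 1, 0 to 547, 0 to 2, 0 to 1, 0 to 1 and 0 to 0 with fulvestrant, SAR439859, GDC-0810, AZD9496, GDC-SAR and AZD-SAR. They ranged over 89 to 114 and 95 to 146 for GDC-SAR against GDC-0810, 133 to 164 and 289 to 2702 for AZD-SAR against AZD9496, 1 to 785 and 0 to 0 for GDC-SAR and 1 to 407 and 0 to 0 for AZD-SAR against SAR439859. They ranged over 485 to 1639 and 252 to 338 for GDC-0810 and 432 to 1886 and 377 to 1086 for AZD9496 against SAR439859, 0 to 273 and 0 to 1 for SAR439859 against fulvestrant, 0 to 5 and 0 to 992 for AZD9496 against GDC-0810, 0 to 1 and 0 to 0 for AZD-SAR against GDC-SAR, 0 to 1 and 0 to 567 for the difference between side chain effects, and 489 to 1178 and 389 to 1491 for the F test.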

Other observations

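The scaffold comparisons and the tests by splits in this part were chosen only after the results were seen.

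The 2 parent scaffolds were also compared with each other at matched doses. At 30 nM 3 genes were higher with AZD9496 than with GDC-0810 (limma, 2728 at unadjusted p < 0.05), TSPAN1, a tetraspanin gene (1.35, 48.6 against 18.7 TPM), FAM117A (0.85) and APEX2, a DNA repair nuclease gene (0.49), each at adjusted p = 0.0476. At 300 nM 161 genes differed (147 higher), a share of 91.3% that scaling moved to 52.9%, led by the metallothionein gene MT1X (1.69, adjusted p = 0.0258) and the actin-severing gene GSN (1.55, 135 ± 20.3 against 46.3 ± 14.1 TPM). The median of all genes at 30 nM lay 0.171 higher before scaling. These counts depend on the setting. Scaling gave 0 and 17 and protein-coding genes only 0 and 0, whereas a block for replicate number gave 590 and 1213 and leaving out the 30 nM SAR439859 libraries 193 and 610. No filter gave 36 and 27, and only the 6 libraries compared 0 and 0. The count at 300 nM went to 0 without GDC-0810 replicate 1 or 2, to 992 without GDC-0810 replicate 3, and to 33, 1 and 1 without AZD9496 replicates 1, 2 and 3. At 30 nM it went to 0 without GDC-0810 replicate 1 or 2 or AZD9496 replicate 1 or 3, to 5 without GDC-0810 replicate 3 and to 1 without AZD9496 replicate 2. ESR1 was not called, at 0.53 (adjusted p = 0.0929) and 0.49 (0.0819). The estrogen-induced list differed by 0.18 [95% interval 0.01 to 0.35] and 0.17 [0.00 to 0.34] and was not called by camera (adjusted p = 0.42 and 0.227), and scaling turned the 30 nM difference to -0.01 and left 0.057 at 300 nM. For its means the exact permutation test gave p = 0.1 and 0.2.

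With the SAR439859 side chain on both scaffolds, AZD-SAR and GDC-SAR differed in 0 genes at each dose (limma, 384 and 518 at unadjusted p < 0.05), and in 1 at 30 nM without GDC-SAR replicate 1, with a block for replicate number or with only the 6 libraries compared. Without the filter 13 and 50 genes were called. The estrogen-induced list differed by -0.02 [95% interval -0.19 to 0.15] and -0.05 [-0.22 to 0.12]. The histone list at 300 nM was called (adjusted p = 0.00712) and lost with an estimated correlation (0.641).

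RN7SL1, a small noncoding RNA, took 110300 ± 4067 TPM with DMSO, against group means of 11970 to 54290 with ligands. SNORA76C, another small noncoding RNA, named after its values were seen, went the opposite way, from 55460 ± 8745 TPM with DMSO to group means of 78870 to 151300. Small noncoding RNA together took 26.2% of TPM with DMSO and 16.1% to 22.8% in the treated groups.

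Exchanging libraries between compared groups gave 10 splits for 3 against 3, too few for a share under 0.05, so no claim is made either way. Against DMSO the real split, 1 of 10, gave the most calls with each ligand, 2753 and 2764 with fulvestrant (highest other 0 and 1), 3668 and 3467 with SAR439859 (155 and 1), 2417 and 2309 with GDC-0810 (1 and 0), 1623 and 854 with AZD9496 (0 and 0), 3247 and 2925 with GDC-SAR (1 and 0), and 2968 and 3682 with AZD-SAR (0 and 2). The same held for the side chain, 185 and 180 on the GDC-0810 scaffold (0 and 1) and 242 and 1234 on the AZD9496 scaffold (1 and 0), and against SAR439859 for GDC-0810, 887 and 355 (11 and 3), and AZD9496, 770 and 1024 (463 and 0). GDC-SAR against SAR439859 gave 37 and 0 (9 and 1). AZD-SAR against SAR439859 gave 8 at 30 nM, reached by 2 of 10 (highest other 12), and 0 at 300 nM (24). SAR439859 against fulvestrant gave 2, reached by 3 of 10 (5), and 0 (0). AZD9496 against GDC-0810 gave 3 and 161 (1 and 0), and AZD-SAR against GDC-SAR 0 and 0 (0 and 1). Between doses 0 genes were called and all 10 splits reached that, with highest others of 0, 53, 0, 9, 0 and 1 for fulvestrant, SAR439859, GDC-0810, AZD9496, GDC-SAR and AZD-SAR. For the F test the real grouping, 1 of 100, gave 736 and 707 (highest other 115 and 586). At 300 nM a random grouping thus came near the real count, and the reason was not tested.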
